A study of Homo sapiens with 2 samples.

How the data were processed

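Single-cell RNA was measured in A549 cells, an established human lung adenocarcinoma line of epithelial type, in 2 libraries. The control library came from cells in 2D culture and the squashed library from cells confined with polydimethylsiloxane (PDMS) micropillars, per the labels' protocols. Both came from live cells sorted for loss of a chromosome reporter after 48 h of recovery, a state of about 1 cell in 500, per the labels' design text. The chromosome that carries the reporter is not given in the sources used here. Groups were taken from the treatment label. The labels record 1 batch for both libraries.

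The libraries were made with a 10x Genomics Chromium 3.1 single-cell kit, which tags each captured molecule with a unique molecular identifier (UMI), and were sequenced on a NovaSeq 6000 with 100 cycles, per the labels' design text. The files hold counts of UMIs per gene and barcode as the authors deposited them, whole numbers without normalization, per the file headers. The counting was done with Cell Ranger against 10x Genomics' GRCh38 reference; its version is 5.0.1 per the labels' design text and 4.0.0 per the file headers. R 4.3.2 is named per the submitters' processing notes, with no step given for it. The rule by which barcodes were called cells is not given in the sources used here. The files list 36601 genes.

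From these counts the following was computed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2, scikit-learn 1.9.0, matplotlib 3.10.9 and edgeR 4.0.16 in R 4.3.3. Cells were kept with at least 1000 UMIs, at least 500 genes and at most 20% mitochondrial UMIs. Doublets were called per library with Scrublet in scanpy, which marked 16 control and 15 squashed cells; these were kept, and left out as an alternative. For values that depend on depth, cells were thinned to 2000 UMIs, the largest of several fixed numbers that kept at least 80% of each library's cells; 1825 control and 1782 squashed cells were that deep. Gene positions, transcript lengths (the annotation's canonical transcript) and GC content came from GENCODE 44 on GRCh38, matched by gene identifier for 36366 of the 36601 genes.

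UMIs were summed over the kept cells of each library and scaled by the library's total UMIs to CPM. The log2 ratio of squashed over control used a prior of 0.5 count. Genes with at least 20 CPM in either library were called measured. With 1 library per group there is no replicate error, so no test was made and no p-value is given; every 95% interval of a ratio or share is an exact Clopper-Pearson interval that covers counting error only, and the ratios compare 2 libraries, not 2 conditions. Medians over genes have an exact order-statistic interval over those genes, which for the shortest lists is the range of the members. A list's median was also placed among 10000 random lists of the same size drawn from 10 bins of mean expression, as a description of these libraries; the draws were not matched on length or GC content.

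Choices of groups, filters, gene lists, comparisons and most alternatives were fixed before the data were examined. There were 36 gene lists. Named genes are the 12 highest and the 12 lowest ratios among genes with at least 50 CPM in either library, without mitochondrial genes, then up to 4 measured members with the largest absolute ratio of each described list, and always LMNB1, LMNA, MKI67, TOP2A and CDKN1A. A further gene and a list fixed in advance are not reported here. MT2A was named after its values had been seen. Phases were called with scanpy from the lists of G1/S and G2/M genes on thinned cells. Cells were clustered jointly on 2000 variable genes, 30 principal components and 15 neighbours, with Leiden resolution 0.5. Clusters are given by number, since the files used here hold no cell annotation. A clustering with each gene centred within its library, which gave the states described in the text, was added after the joint clusters had been seen.

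Chromosome values used genes with 10 to 500 CPM, without the G1/S and G2/M lists. A cell's chromosome dose is the share of its UMIs over these genes that fell on the chromosome, divided by the median of all cells, and a cell under 0.75 was counted as low; the share that counting alone gives was drawn from each library's mean profile. Added after the data had been seen were a run on cells with at least 10000 UMIs thinned to 10000, a fit of 2 normal ranges with a common SD to the dose in those cells, and the removal of the metallothionein genes of chromosome 16 (MT1A, MT1F and MT1X) from that fit. The fit with them included gave no usable upper range in the squashed library, because a few cells had very high MT1X. The boundary between the ranges was the midpoint of the fitted means in state 2, and the same boundary was used for both libraries. Classes of transcript length and GC content were also chosen after the ratios had been seen.

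The scripts' steps were tested on simulated data. For the gene ratios, counts of 4018 genes were drawn from the libraries' means with 200 genes altered. All 50 genes made 3-fold higher and all 50 made 3-fold lower passed 2-fold, and 0% of the genes made 1.5-fold higher or lower did, since that size is under the rule. The intervals held the true ratio for 94% and 100% of the 3-fold genes and for 92% and 96% of the 1.5-fold genes, and 0 of 3818 unaltered genes passed 2-fold. A list of 24 genes with a true log2 ratio of 0.38 was measured at 0.39. For chromosome 16 dose, 300 of 1000 simulated cells were given 2 of 3 copies. At 2000 UMIs 50.7% of these and 4.71% of the others fell under the threshold, and the fit of 2 ranges put 64.6% of cells in the lower range, so it was not used at that depth. At 10000 UMIs the threshold took 66.7% and 0%, and the fit gave 30.6% of cells in the lower range with a ratio of the means of 0.676. The simulated cells held no states and no variation in expression between cells, so these shares need not hold in the data.

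Alternatives were a wider and a stricter cell filter, removal of doublet calls, edgeR's TMM scaling, scaling without mitochondrial or ribosomal protein genes, equal weight per cell, thinned cells, another pseudocount, other expression minimums, G1 cells alone, single states, and other settings of phase, cluster and dose. Values by state 4, which held 98 cells, were left out. Y-linked genes and the X-inactivation transcripts were left out of every gene-level value. No DNA data and no reporter-positive cells were analysed here, so no value compares reporter-negative with reporter-positive cells.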

Results

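The study concerns A549 cells that lost a chromosome reporter, a rare event in this lung adenocarcinoma line, and asks whether a past period of confinement leaves such cells with altered chromosomes and an altered division program. The control library held 2574 barcodes with 30565366 UMIs, and the squashed library held 3132 barcodes with 26829300 UMIs. After filtering, 1906 control cells (74.0% of barcodes, 95% interval 72.3 to 75.7) and 1930 squashed cells (61.6%, 59.9 to 63.3) remained. Control cells were deeper, with a median of 12459 UMIs and 2598 genes against 9331 UMIs and 1790 genes in squashed cells, and the median mitochondrial share was 5.77% against 7.10%. The kept cells held 27482392 and 23328323 UMIs. All intervals cover counting error only, and 1 library per group gives no check by replicates.

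Clustering with every gene centred within its library, which removes the average difference between the libraries by construction, gave 5 states that each held cells of both. State 2 was led by genes of mitosis and cytokinesis such as TOP2A, RACGAP1, HMMR and KIF23, and 95.8% of its control cells and 91.9% of its squashed cells were called G2/M. State 1 was led by nuclear non-coding RNAs such as NEAT1 and KCNQ1OT1 together with FOS and SOX4; its cells were the deepest, with medians of 21732 and 23466 UMIs. State 3 was led by MTRNR2L8 and MT-ND6 together with the mitotic genes CDC20 and AURKB, state 0 by ANXA10 and MAP1B in cells with medians of 1387 and 1303 genes, and state 4 held 98 cells with almost no mitochondrial UMIs. Of states 0 to 3, state 0 had the least nuclear non-coding RNA, 201 CPM in the control and 334 CPM in the squashed library. Its share of ribosomal protein UMIs was the highest, 41.4% and 40.0%. State 0 held 35.9% of squashed cells (33.7 to 38.2) and 15.3% of control cells (13.7 to 17.1). States 1, 2 and 3 held smaller shares of the squashed than of the control library, at 19.4% against 24.4%, 25.1% against 33.0% and 17.1% against 24.3%. State 0 cells held fewer genes than those of states 1, 2 and 3, the libraries differ in depth and in the share of barcodes removed, and the state shares were not examined under another filter or depth.

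Without centring, the libraries separated. Of 3607 cells, 51.1% lay in 2 of 5 clusters that drew at least 90% of their cells from 1 library, and AURKA, CCNB1, PLK1 and CDC20 were among the leading genes of both. Mitotic cells of the control and squashed libraries were thus placed in separate clusters, and the sizes of these clusters are not compared here. At resolution 1.0 the share of cells in such clusters was 75.6%, and after centring it was 0 of 3607 cells, largely by construction (a share of up to 0.102%).

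**Figure D1:**
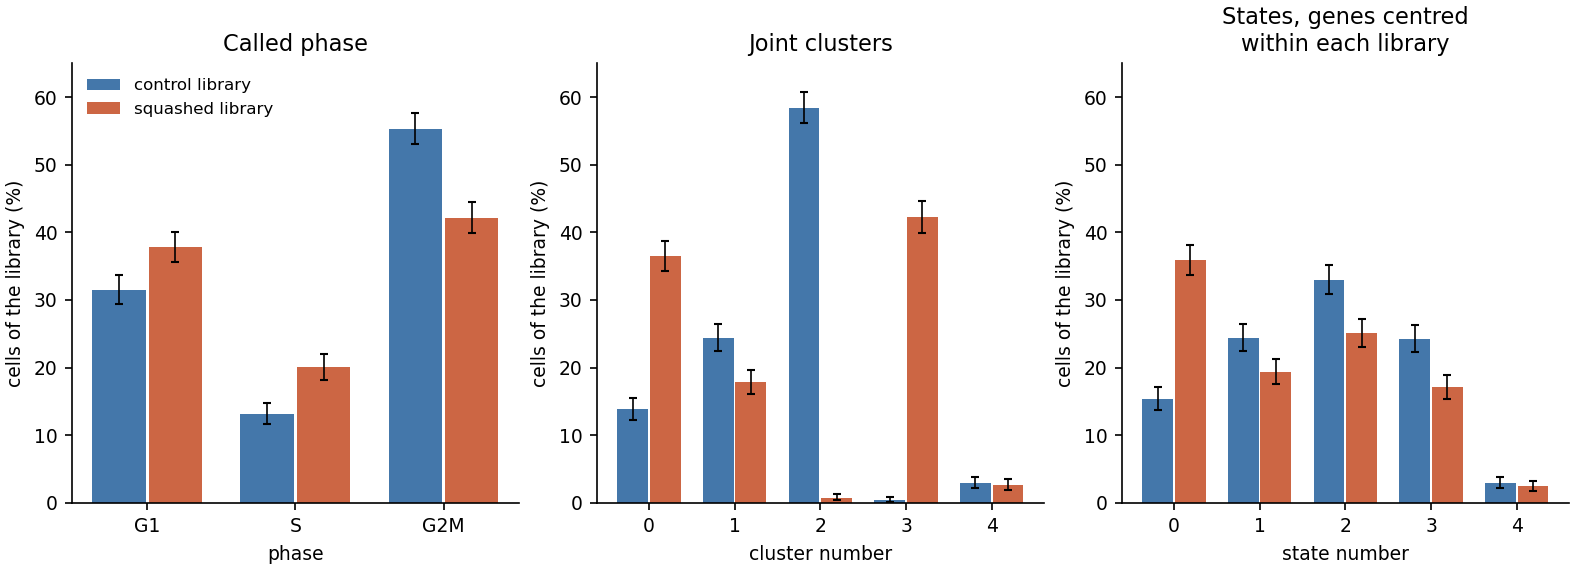
Percent of each library's cells in each called phase, joint cluster and state, with 95% exact binomial intervals that cover counting error only (1825 control and 1782 squashed cells). Joint clusters 2 and 3 drew nearly all their cells from 1 library, whereas each state held cells of both.

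Across the 4307 measured genes, 220 were at least 2-fold lower and 47 at least 2-fold higher in the squashed library, counted by size and not by a test. Among the lowest genes were MRPL12 and MRPL34, proteins of the mitochondrial ribosome, NDUFAB1, the mitochondrial acyl carrier protein, and TSPO of the outer mitochondrial membrane. MRPL12 stood at 95.7 CPM in the control and 7.93 CPM in the squashed library (log2 ratio -3.59, -3.82 to -3.38), MRPL34 at 68.8 and 13.2 CPM (-2.37, -2.55 to -2.20), NDUFAB1 at 117 and 17.9 CPM (-2.71, -2.86 to -2.56), and TSPO at 131 and 28.3 CPM (-2.21, -2.33 to -2.09). PPDPF was 8.52-fold lower (-3.09, -3.21 to -2.97) and DDT, a tautomerase related to MIF, was 7.57-fold lower (-2.92, -3.05 to -2.80). The other 6 of the 12 lowest genes were AURKAIP1, BAD, JAGN1, RNH1, IER3 and PDCD6, between -2.41 and -2.16; BAD promotes apoptosis and IER3 is an immediate early gene. The highest genes encode small proteins or short non-coding RNAs for the most part. ATP5ME, a small subunit of ATP synthase, stood at 148 and 566 CPM (1.93, 1.88 to 1.99), NDUFB1 of complex I at 173 and 619 CPM (1.84, 1.79 to 1.89), and the ribosomal protein gene RPS29 at 1771 and 6081 CPM (1.78, 1.76 to 1.79). The non-coding host genes SNHG25 and SNHG19 had log2 ratios of 1.85 and 1.74, and the metallothionein MT1X, which binds zinc and copper, 1.65 (1.59 to 1.72). PRR34-AS1, SMIM4, CNFN, PET100 and PEG10 lay between 1.52 and 1.73. ISG15, an interferon-induced ubiquitin-like protein, stood at 35 and 99 CPM (1.5, 1.39 to 1.61). The genes lie on many chromosomes; in GRCh38 coordinates MRPL12 (ENSG00000262814) spans chromosome 17 from 81703367 to 81707517, PPDPF (ENSG00000125534) chromosome 20 from 63520765 to 63522206, ATP5ME (ENSG00000169020) chromosome 4 from 672436 to 674330 and MT1X (ENSG00000187193) chromosome 16 from 56682470 to 56684196.

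The ratios of MRPL12 and ATP5ME were much the same in each state, MRPL12 lying between -3.76 and -3.32 and ATP5ME between 1.77 and 2.24 over states 0 to 3, whereas MT1X ranged from 0.66 in state 1 to 2.96 in state 2. Transcript length ran with the ratio: of 60 measured genes with transcripts up to 500 nt, 15 were at least 2-fold higher and 1 was lower, against 31 higher and 219 lower of 4242 longer ones. The median ratio was 1.2 (0.89 to 1.74) for 20 transcripts up to 400 nt, 0.42 (0.24 to 0.48) for 40 over 400 and up to 500 nt, -0.04 for 235 over 500 and up to 800 nt and -0.15 for 4007 over 800 nt. Among the 12 highest genes, 7 have transcripts up to 500 nt: ATP5ME, SNHG25, NDUFB1, RPS29, SNHG19, PRR34-AS1 and MT1X. Genes with a GC content over 65% had a median of -0.63 (-0.99 to -0.35, 40 genes), and PPDPF, AURKAIP1 and BAD are among them. TMM scaling moved the median log2 ratio of all measured genes from -0.14 to 0.03 and the counts to 156 genes lower and 68 higher, so group medians are given below as well relative to that of all genes. RPS29, MT1X, DDT and the HLA genes have near-identical copies, and their values are uncertain as far as reads were split among copies.

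**Figure D2:**
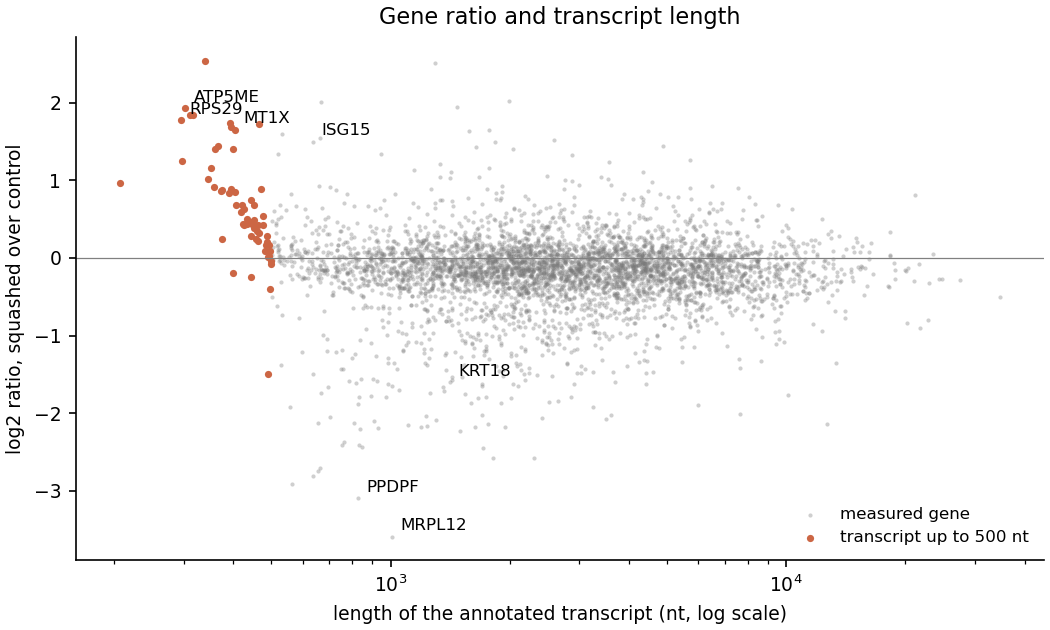
Log2 ratio of squashed over control CPM against the length of the annotated transcript (nt, log scale), 1 point per measured gene, with transcripts up to 500 nt in orange. The shortest transcripts sit above 0, with a median of 1.2 up to 400 nt, and most strongly lower genes such as MRPL12 and PPDPF have longer transcripts.

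Genes of DNA replication and of mitosis differed little between the libraries as groups. Of 24 measured G1/S genes, which serve DNA replication, 23 lay within 1.5-fold, 0 were higher and 1 was lower by that size. Their median log2 ratio was 0.03 (-0.12 to 0.12), 0.17 above that of all genes and at the 99.8th percentile of random lists. It lay under the median of all genes with the stricter cell filter and with thinned cells. The whole list summed to 1259 CPM in the control and 1221 CPM in the squashed library (-0.04, -0.07 to -0.02). Of 49 measured G2/M genes 45 lay within 1.5-fold, with a median of -0.19 (-0.28 to -0.07) that was 0.05 under that of all genes, although it lay 0.33 above it in cells called G1; TMPO (-0.76), the motor KIF11 (-0.66) and the spindle protein TACC3 (-0.65) were lower and CDK1, the mitotic kinase, was higher (0.74, 0.60 to 0.88). Genes of the spindle checkpoint and kinetochore summed to 1588 CPM in the control and 1301 CPM in the squashed library (-0.29, -0.31 to -0.27), with all 14 measured members within 1.5-fold and a median 0.06 under that of all genes, though above it in cells called G1. Among them the checkpoint kinase BUB1B (-0.45), ZWINT (-0.44), the securin PTTG1 (-0.44) and MAD2L1 (-0.42) had the largest ratios, whereas PTTG1, ZWINT and MAD2L1 were higher within state 1 and BUB1B within state 3. Genes of cytokinesis and mitotic motors had a median of -0.07 (-0.23 to 0.01, 23 genes), with CEP55 at -0.44, the kinase AURKB at -0.43 and the septin SEPTIN9 at -0.33, and 22 of them lay within 1.5-fold; CEP55 and AURKB were higher within state 1. TOP2A, the topoisomerase of dividing cells, was higher (342 and 479 CPM; 0.49, 0.45 to 0.53) except within state 0, and the proliferation marker MKI67 was close (123 and 118 CPM; -0.06, -0.14 to 0.01).

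The medians of the division groups within states had wide intervals, most of which span 0. In state 1 the G2/M list had a median of 0.15 (-0.02 to 0.25, 44 genes), the G1/S list 0.35 (0.13 to 0.50, 22 genes) and the spindle checkpoint list 0.21 (-0.06 to 0.46, 13 genes). In state 2, which holds most mitotic cells, they were -0.04 (-0.11 to 0.12, 54 genes), 0.03 (-0.16 to 0.22, 26 genes) and -0.09 (-0.31 to 0.03, 20 genes). In state 0 the G2/M list had a median of -0.50 (-0.77 to -0.13, 17 genes), and the G1/S list 0.32 (-0.22 to 0.91, 7 genes), where the median of all genes was 0.12. Differences between states were not tested.

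At a common depth of 2000 UMIs a smaller share of squashed cells was called G2/M, 42.1% (39.8 to 44.5) against 55.3% (53 to 57.6) of control cells. S calls made up 20.03% (18.2 to 22) against 13.2% (11.6 to 14.8), and G1 calls 37.8% (35.6 to 40.1) against 31.5% (29.4 to 33.7). Without thinning the G2/M shares were 48.6% and 61.8% and the S shares 3.37% and 2.30%. Within states 0 to 3 the gaps were smaller. Squashed then control, G2/M calls were 6.25% and 9.29% in state 0 and 20.2% and 13.5% in state 1. They were 91.9% and 95.8% in state 2 and 70.8% and 75.8% in state 3. State 0, with few G2/M calls, held a larger share of the squashed library. How far state shares account for the difference in calls was not tested. Summed over all kept cells, G2/M genes made up 6165 CPM in the squashed and 6622 CPM in the control library (-0.10, -0.11 to -0.09). The sum weights cells by their UMIs, whereas the calls count each cell once. The sizes of these differences are therefore not compared. RNA free in the droplets was not estimated, and the calls alone are not read as cycling.

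Among genes of the unfolded protein response, which refit the endoplasmic reticulum to protein load, some were much lower in the squashed library. Of 12 measured members 5 were at least 1.5-fold lower, 7 within that size and 0 higher, with a median of -0.43 (-1.10 to -0.23), 0.30 under that of all genes and at the 0.06th percentile of random lists. The secreted factor MANF stood at 40.0 and 9.30 CPM (-2.10, -2.32 to -1.89), HERPUD1 at -1.79, and the chaperones CALR and DNAJB11 at -1.10 and -1.05. The list's median was -0.72 (-1.51 to -0.45) in state 1, -0.30 in state 0, -0.26 in state 3 and -0.16 (-1.0 to 0.14) in state 2. Genes of the nuclear envelope, the membrane and lamina around the chromosomes, had a median of -0.32 (-0.76 to -0.09, 12 genes), 0.18 under that of all genes; 4 were at least 1.5-fold lower, namely TOR1A (-1.35), SYNE2 (-0.90), TMPO (-0.76) and TPR (-0.62). SYNE2, which links the nucleus to the cytoskeleton, was higher within states 2 and 3. The lamin genes themselves were close, LMNB1 at 13.8 and 12.1 CPM (-0.19, -0.42 to 0.04) and LMNA at 113 and 119 CPM (0.07, -0.01 to 0.14).

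Epithelial and mesenchymal genes were split. The paired keratins of simple epithelia went apart, KRT18 being 3.04-fold lower (1691 and 557 CPM; -1.60, -1.63 to -1.57) and KRT8 1.47-fold higher (796 and 1168 CPM; 0.55, 0.53 to 0.58), and the junction protein JUP (-1.0) and KRT80 (-0.80) were lower; JUP was higher within state 3. The 6 measured epithelial genes had a median of -0.38 (-1.60 to 0.55), 0.25 under that of all genes, and lay above it in 2 of 12 alternatives. Among 12 measured genes of epithelial-mesenchymal transition the tropomyosin TPM1 (-1.22) and fibronectin FN1 (-0.91) were lower, the integrin ITGAV was at -0.41 and N-cadherin CDH2 at 0.40, while the list's median was 0.13 (-0.41 to 0.33), 0.27 above that of all genes. FN1 was higher in the squashed library with the stricter cell filter and within states 2 and 3. Interferon genes were also split, with ISG15 and IFI35 (0.41) higher and the antigen-presenting HLA-B (-1.37) and HLA-C (-1.06) lower; IFI35 was lower within state 2. Of 7 measured hypoxia genes 3 were at least 1.5-fold lower, namely DDIT4 (-1.80), BNIP3 (-1.09) and ADM (-0.94), and 1 higher, the collagen hydroxylase P4HA1 (0.89); ADM was higher within state 0.

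Genes of energy metabolism lay above the median of all genes. Glycolysis genes had a median of 0.23 (0.09 to 0.38, 12 genes), 0.36 above that of all genes and at the 99.4th percentile of random lists, with 11 of the 12 within 1.5-fold, 0 higher and 1 lower by that size. The lower gene was PGAM1 (-1.01, -1.07 to -0.95), and GPI (0.47), the lactate exporter SLC16A3 (0.46) and PFKM (0.38) had the largest ratios above 0. Nuclear genes of oxidative phosphorylation had a median of 0.12 (0.02 to 0.33, 34 genes), 0.25 above that of all genes, with ATP5ME, ATP5F1E (0.94) and UQCRQ (0.78) higher and NDUFB10 lower (-0.99); 8 of the 34 have transcripts up to 500 nt, the class that was higher throughout. Of 27 proteasome genes 26 lay within 1.5-fold, with a median of 0.06 (-0.06 to 0.17), 0.19 above that of all genes; the exception was PSMD8 of the regulatory particle at 516 and 177 CPM (-1.54, -1.59 to -1.49), while PSMD2 was at -0.51, PSMD14 at 0.48 and PSMB7 at 0.30. CDKN1A, an inhibitor of cyclin-dependent kinases, was 1.53-fold higher (62.4 and 95.5 CPM; 0.61, 0.52 to 0.71).

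Markers of other cell types were scarce. The fibroblast list had 0 measured members and summed to 8.08 CPM in the control and 6.64 CPM in the squashed library. The immune list had 1 measured member, the lysosomal protein gene CD68 (13.4 and 21.8 CPM), and the endothelial list 1, the secreted factor EGFL7 (44.8 and 10.2 CPM; -2.14, -2.35 to -1.94).

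**Figure D3:**
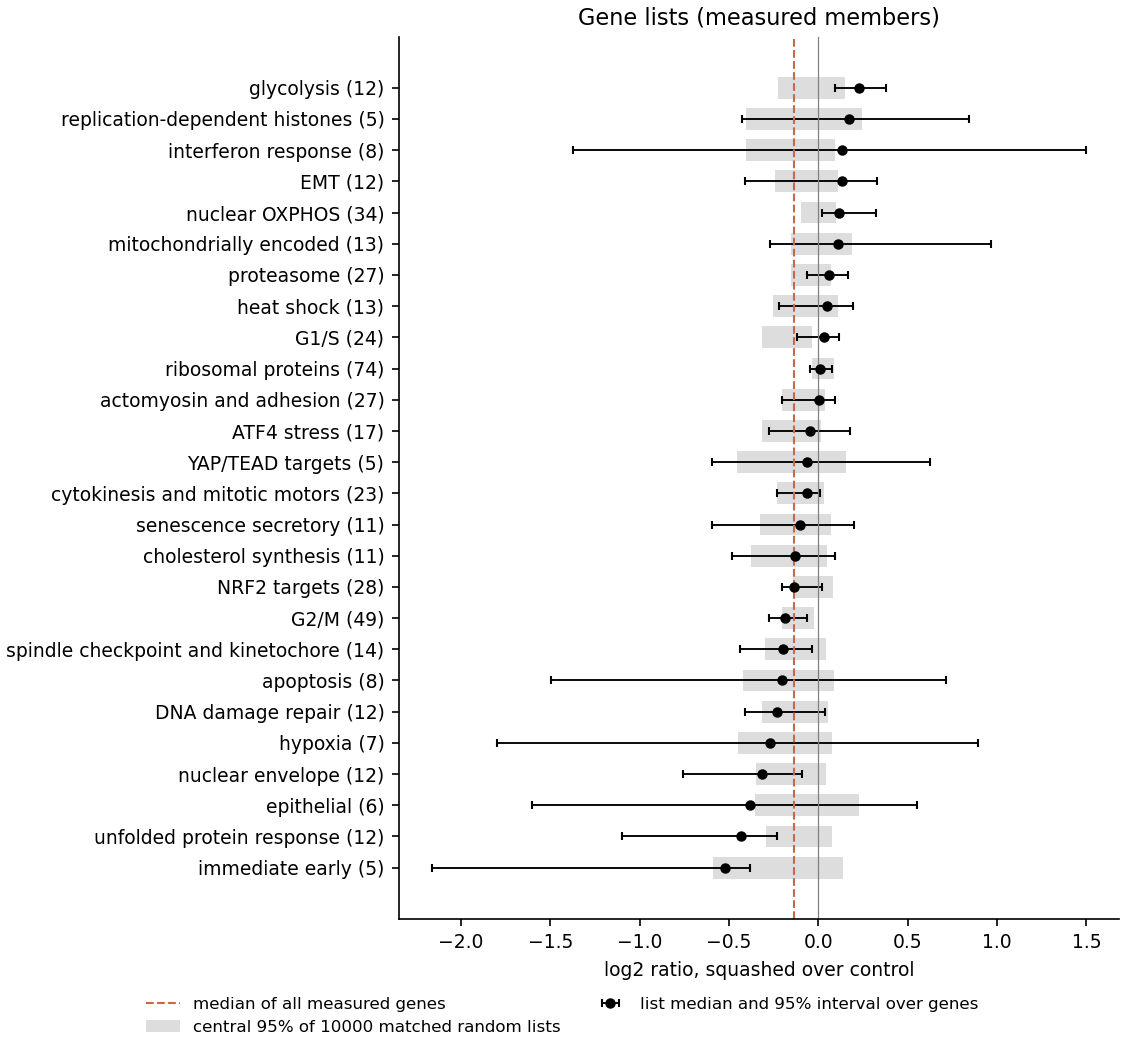
Median log2 ratio of squashed over control for the reported gene lists with at least 5 measured members (number in brackets), with its 95% interval over genes, the central 95% of 10000 expression-matched random lists in grey and the median of all measured genes as a dashed line. Unfolded protein response genes lie under the random range at -0.43 and glycolysis genes above it at 0.23.

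Summed over cells, no chromosome stood far from the rest. Over 6122 genes in the chromosome set the median log2 ratio was -0.17, and the medians of the 23 chromosomes ran from -0.25 to -0.10. Outside the central 95% of random lists lay 5 of them: chromosomes 8 (-0.21, -0.25 to -0.18), 19 (-0.22, -0.25 to -0.17) and 20 (-0.23, -0.31 to -0.18) were lower, and 4 (-0.12, -0.16 to -0.04) and X (-0.10, -0.14 to -0.06) higher. Chromosomes 5 (-0.14, -0.20 to -0.11) and 16 (-0.17, -0.20 to -0.12) lay inside. Of 41 arms 5 lay outside, namely 4q, 8p, 19p, 20q and Xq. The random lists were not matched on length or GC content, which ran with the ratio.

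**Figure D4:**
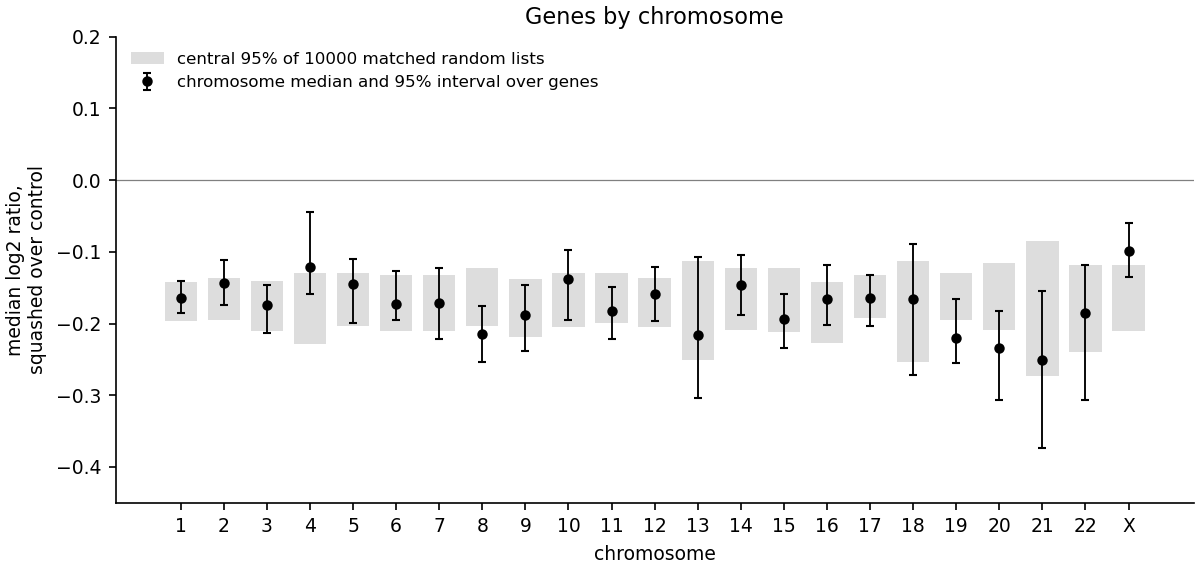
Median log2 ratio of squashed over control by chromosome over genes with 10 to 500 CPM, with 95% intervals over genes and the central 95% of 10000 expression-matched random lists in grey. All 23 medians lie between -0.25 and -0.10, and chromosomes 4, 8, 19, 20 and X lie outside their grey range.

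For every chromosome but chromosome 13, more cells at 2000 UMIs had a low dose than counting alone gives, as averaged over the libraries. The counting draw holds no variation in expression between cells, so an excess need not mean fewer copies. The averaged excess at this depth was largest for chromosome 16. At that depth 17.8% of control cells (16.1 to 19.6) and 27.3% of squashed cells (25.3 to 29.5) had a chromosome 16 dose under 0.75, where counting alone gives 8.0% and 15.2%. The next largest were chromosome 17, with 11.3% of control and 13.2% of squashed cells against 4.0% and 5.22%, and chromosome 5, with 16.2% and 14.5% against 8.77% and 7.30%. These values rest on few UMIs, a median of 19 in control and 15 in squashed cells on chromosome 16, and 157 and 176 cells lay between 0.7 and 0.8. In the 1190 control and 906 squashed cells with at least 10000 UMIs the shares under 0.75 for chromosome 16 were 6.97% and 12.8%, where counting gives 0.0840% and 0.221%. At that depth chromosome 16 was not the largest. Chromosome 5 had 14% in the control and 15.1% in the squashed library against 0.504% and 0.331%. Chromosome 20 had 10.0% and 14.5% against 0.756% and 1.32%. Chromosome 17, with 8.40% and 7.06% against 0% and 0.110%, was above chromosome 16 in the control only. Most low-dose cells of chromosome 5 were in state 1, 157 of 167 in the control and 124 of 137 in the squashed library. State 1 as a whole lay low on this chromosome. A fit of 2 ranges put its lower mean at 0.779 and 0.774, with only 7.77% and 2.51% of its cells in the upper range. In state 2 the fitted lower means were 1.06 and 1.08. Low dose of chromosome 5 was thus mostly part of a shift of the whole state. For chromosome 16, with the metallothionein genes left out, 33 of 86 control and 41 of 123 squashed low-dose cells were in state 1. Only 2 and 8 were in state 2, and 0 and 2 in state 3. The rest, the larger part in each library, were in states 0 and 4, and state 0 held a larger share of the squashed library. Within state 1 the low-dose shares were 7.60% and 12.5%. How far state shares account for the difference between the libraries was not tested.

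Within the mitotic state 2, chromosome 16 dose fell into a lower and an upper range in each library, a fit made after these shares had been seen; the lower range lies around the median of all cells, so few of its cells lie under 0.75. In the control library the fitted means were 1.00 and 1.44, a ratio of 0.695, with 35.9% of 486 cells in the upper range. In the squashed library they were 0.957 and 1.34, a ratio of 0.714, with 45.2% of 322 cells in the upper range. Over a common boundary of 1.2 lay 38.9% of control (34.5 to 43.4) and 41.0% of squashed cells (35.6 to 46.6), a difference within the intervals, with 30 and 42 cells within 0.05 of the boundary. Both squashed means lie under those of the control, so this boundary may undercount the squashed upper range. The closeness of these shares thus depends on the boundary. In state 1 the shares over the boundary were 20.3% (16.6 to 24.4) and 18% (14 to 22.6), in state 3 38.7% (29.9 to 48.0) and 30.4% (19.9 to 42.7), and over all states 28.8% (26.3 to 31.5) and 24.2% (21.4 to 27.1). The ranges were not particular to state 2. The fit gave ratios of the means, control then squashed, of 0.701 and 0.678 in state 1 and 0.690 and 0.688 in state 3. The ranges are cut from a per-cell value and are not cell types.

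**Figure D5:**
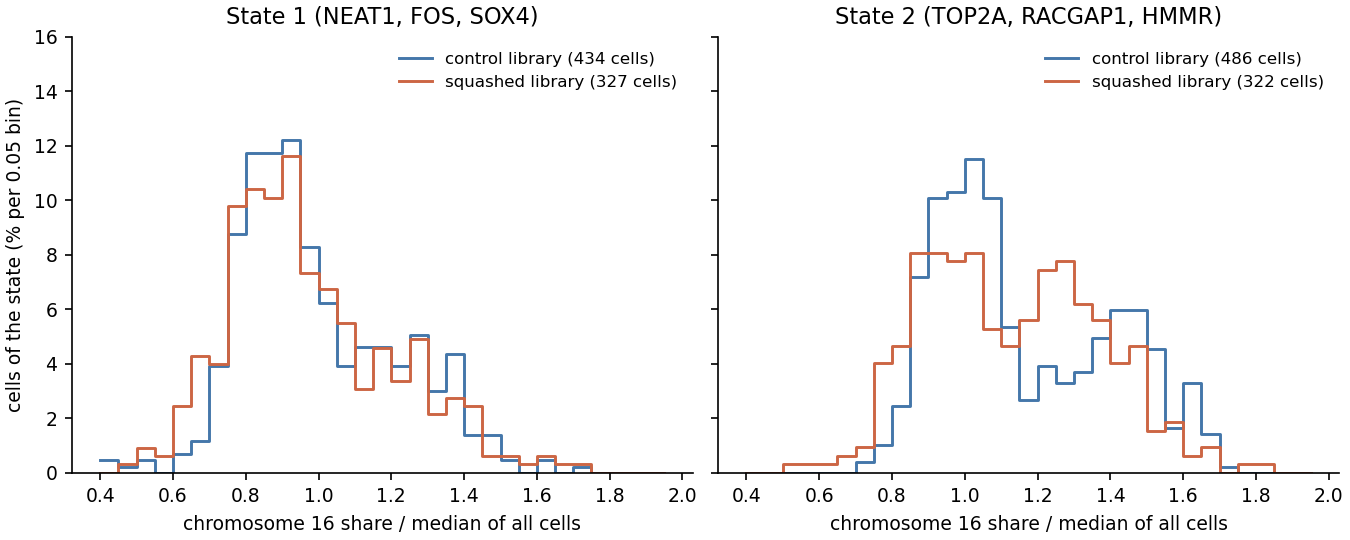
Distribution of chromosome 16 dose (the cell's share of UMIs on chromosome 16 divided by the median of all cells) in cells with at least 10000 UMIs, as percent of cells per bin of 0.05, for states 1 and 2 of each library. State 2 shows a lower and an upper range in both libraries, with fitted means of 1.00 and 1.44 in the control and 0.957 and 1.34 in the squashed library.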

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

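These shares were compared only after the barcodes had been filtered, and concern barcodes that were removed from all values except those without a cell filter. In the squashed library 30.5% of barcodes (28.9 to 32.2; 956 of 3132) had over 20% mitochondrial UMIs, above the 19.7% (18.1 to 21.2; 506 of 2574) of the control library. Barcodes with under 500 genes made up 21.5% (20.1 to 23; 673 of 3132) of the squashed and 14.9% (13.6 to 16.4; 384 of 2574) of the control library. The shares under 1000 UMIs were 10.1% and 10.3%.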

How the results depend on the processing

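Values for single states, for phases scored in each library alone, for clusters after centring and for cells with at least 10000 UMIs were chosen after seeing the data; the other alternatives were planned. They were tabulated for the named genes of the described lists and for the chromosomes named here, a selection made after the values were known. No paired analysis was possible because each group has 1 library. Relative to all genes the unfolded protein response, nuclear envelope and hypoxia lists stayed under and the glycolysis, oxidative phosphorylation, proteasome, interferon and epithelial-mesenchymal transition lists above in 12 of 12 settings of filter, doublets, depth, scaling, pseudocount, minimum and phase, in which the unfolded protein response list ranged from -0.60 to -0.20 and the glycolysis list from 0.27 to 0.67. Single states went beyond this: relative to all genes the unfolded protein response list was at -0.11 in state 2 and the glycolysis list at 0.075 in state 3, the hypoxia list was above in states 0 and 1, and the interferon list under in states 0, 2 and 3, the epithelial-mesenchymal transition list under in state 0 and the proteasome list in states 2 and 3. Of the single-gene values, 837 stayed within the counting interval, 502 left it without turning a called direction and 21 turned. Depth limits the dose values, since a thinned cell holds few UMIs per chromosome. Where a value below differs, the cause was not tested, unless the setting itself sets it.

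TMM scaling adds 1 constant to every log2 ratio and gave medians of 0.18 for G1/S, -0.036 for G2/M, 0.086 for cytokinesis, -0.35 for immediate early, 0.20 for heat shock, 0.38 for glycolysis, 0.79 for NF-kB, 0.15 for actomyosin, 0.16 for ribosomal protein and 0.21 for proteasome genes. The stricter cell filter gave -0.18 for G1/S, -0.30 for G2/M, -0.18 for immediate early, -0.086 for proteasome and 0.31 for nuclear non-coding RNA genes, and turned FN1 to 0.11. Equal weight per cell gave -0.13 for G1/S, -0.32 for G2/M and -0.81 for nuclear non-coding RNAs, and thinned cells gave -0.22, -0.37 and -0.89. In cells called G1 the G2/M list turned to 0.10 and RAD51AP1 to 0.28, and the medians were 0.041 for cytokinesis, -0.57 for DNA repair, 0.43 for glycolysis, 0.16 for cholesterol synthesis, -0.067 for NF-kB, 0.33 for oxidative phosphorylation and 0.21 for proteasome genes. With a minimum of 5 CPM the NF-kB list was at -0.17.

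The count of lower genes, 220, became 455 with a minimum of 5 CPM and 109 with a minimum of 50 CPM, which alter the genes counted, 367 in cells called G1 and 117 in state 0. The count of higher genes, 47, became 93 with a minimum of 5 CPM, 98 in state 0 and 85 in state 1. Genes of the lists not described in detail were not tabulated, and some of these also turn by state. Among the tabulated ones directions turned in state 0 for CDCA7 (0.53), ADM (0.87) and TOP2A (-0.50), in state 1 for MAD2L1 (0.18), PTTG1 (0.46), ZWINT (0.25), CEP55 (0.14), AURKB (0.038) and the histone H2AFZ (0.55), in state 2 for FN1 (0.29), SYNE2 (0.29) and IFI35 (-0.17), and in state 3 for FN1 (0.17), SYNE2 (0.12), BUB1B (0.090), JUP (0.15), CD68 (-0.086) and the linker histone H1F0 (0.10).

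In cells called G1 the chromosome medians were -0.25 for 4, -0.28 for 5, -0.36 for 8, -0.42 for 16, -0.40 for 19, -0.47 for 20 and -0.19 for X. The stricter filter gave -0.037 for 4, -0.11 for 5, -0.10 for 16 and -0.038 for X, and genes with at least 5 CPM gave -0.16 for 4. The median of all measured genes moved as well, from -0.14 to -0.24 in cells called G1 and to -0.12 with the stricter filter. Part of the shift in G1 cells was thus common to all genes. The share of cells with low chromosome 16 dose, control then squashed, was 15.9% and 20.3% with genes of at least 5 CPM, 11.8% and 19.6% under 0.67, 20.7% and 24.5% against the library's own median and 6.97% and 12.8% at 10000 UMIs, and 29.8% of squashed cells called G1. For chromosome 17 it was 3.67% and 5.72% with genes of at least 5 CPM, 7.01% and 7.01% under 0.67, 8.40% and 7.06% at 10000 UMIs, and in the control 9.81% with the stricter filter and 16.9% in G1. For chromosome 5 it was 11.2% and 9.08% with the stricter filter, 8.77% and 7.69% under 0.67, in the control 18.6% in G1, 13.8% against its own median and 14% at 10000 UMIs, and in the squashed library 12.1% with genes of at least 5 CPM.

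Unthinned cells gave G1, S and G2/M calls of 35.9%, 2.30% and 61.8% in the control and 48.0%, 3.37% and 48.6% in the squashed library. Without the cell filter G1 and G2/M calls were 36.3% and 51.8% in the control, and G2/M calls 39.6% in the squashed library. The stricter filter gave 23.9%, 11.2% and 64.9% in the control and 35% G1 in the squashed library. Without doublets G1 was 40.5% of squashed cells, and scored alone the squashed library had 25.4% S and 37.9% G2/M. G2/M calls stayed more frequent in the control library in each of these, but not within state 1. The stricter filter kept 47.5% of control and 34.1% of squashed barcodes, and no filter 100% by construction. Cells in clusters of 1 library were 75.6% at resolution 1.0 and 0% after centring.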

Other observations

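All tests of explanations in this part were chosen after the results had been seen. The histone gene HIST1H4C, a replication-dependent H4 histone, was 1.80-fold higher in the squashed library as a whole (281 and 505 CPM, log2 ratio 0.85, 0.80 to 0.89). Its largest ratios were in the mitotic states 2 and 3, but the rise was not particular to them. In state 0, where most cells were called G1, it stood at 12.6 CPM in the control and 48.4 CPM in the squashed library (1.92, 1.46 to 2.44). HIST1H4C has a transcript up to 500 nt, a class with a median of 0.52 over all cells, 0.62 in state 0, 0.69 in state 1 and 0.51 in state 2. Over all cells and in state 1 its ratio stays within what short transcripts showed. In state 2 it stood at 14.1 CPM in the control and 221 CPM in the squashed library (3.97, 3.71 to 4.24) and in state 3 at 8.46 and 49.1 CPM (2.52, 1.97 to 3.14), whereas in state 1, where it is abundant, it stood at 688 and 1178 CPM (0.78, 0.73 to 0.82). CDK1 went the same way, with 9.31 and 48.2 CPM in state 2 (2.37, 2.03 to 2.73) and 52.8 and 67.9 CPM in state 1 (0.36, 0.19 to 0.54), as did CDKN1A, with 12.6 and 32.0 CPM in state 2 (1.35, 1.02 to 1.69) and 131 and 189 CPM in state 1 (0.53, 0.42 to 0.63). In states 0 and 3 of the squashed library HIST1H4C stood at 48.4 and 49.1 CPM and CDK1 at 11.9 and 10.3 CPM, lower than in state 2. Of the other measured histone genes the linker histone HIST1H1C was at 0.46, H1F0 at -0.43 and H2AFZ at -0.23.

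Most further gene groups differed little. Targets of NRF2, the oxidative stress regulator that is active in A549, summed to 57968 CPM in the control and 57067 CPM in the squashed library, with 27 of 28 genes within 1.5-fold. Ribosomal protein genes had a median of 0.01 (-0.04 to 0.08, 74 genes), with 11 at least 1.5-fold higher, and 9 members have transcripts up to 500 nt; mitochondrially encoded genes had a median of 0.11 (-0.27 to 0.97, 13 genes). Medians were 0.05 for heat shock (13 genes), -0.05 for ATF4 stress (17), 0.002 for actomyosin and adhesion (27, of which 5 were at least 1.5-fold lower and 0 higher), -0.06 for YAP/TEAD targets (5), -0.10 for secreted senescence factors (11), -0.13 for cholesterol synthesis (11), -0.20 for apoptosis (8) and -0.23 for DNA damage repair genes (12). The whole actomyosin and adhesion list summed to 13301 CPM in the control and 11682 CPM in the squashed library (-0.19). In state 2 it summed to 15562 and 12399 CPM, and in state 3 to 15493 and 11737 CPM. Immediate early genes were an exception to the small differences. Of 5 measured, 2 were at least 1.5-fold lower and 3 within that size (median -0.52, -2.16 to -0.38). Their list lay under the median of all genes in 12 of 12 settings. Lists with few measured members were NF-kB targets (0.64, 3 genes; -0.17 with a minimum of 5 CPM), nuclear non-coding RNAs (-0.69, 3 genes; 0.31 with the stricter cell filter), the cGAS-STING pathway (-0.20, 2 genes) and alveolar type 2 genes (-0.60, 1 gene), and the lists of mechanosensitive channels and red blood cell genes had 0 measured members.

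Single genes varied by state, DDIT4 for instance from -2.10 to -0.11, but the 220 lower genes together had a median of -1.19 in the state nearest 0 and -1.38 in the farthest, which argues against different shares of cell states as the cause for most of them. Loss of whole chromosome regions is argued against by their 10 nearest measured genes, whose median was -0.16 (-0.18 to -0.14) beside -0.13 for the neighbours of all measured genes. The lower genes had a higher GC content, with a median of 55.0% beside 46.1% for all measured genes. At least 2-fold lower were 13 of 40 genes over 65% GC, 53 of 310 over 60% and up to 65%, and 154 of 3952 up to 60%. The medians of these classes were -0.63 (-0.99 to -0.35), -0.24 (-0.29 to -0.17) and -0.13 (-0.14 to -0.12). Lower ratios thus went with higher GC content, but whether GC content is a cause was not tested. Length-dependent recovery of short transcripts may account for part of the higher genes, as 48 transcripts up to 500 nt without ribosomal protein and mitochondrial genes had a median of 0.49 (0.35 to 0.74) against -0.14 (-0.15 to -0.13) for longer ones. It leaves 31 higher genes with longer transcripts, and 219 of the 220 lower genes have them. Confinement and a difference in how the libraries were made both stay open for the rest, and 1 library per group cannot separate them.

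The lower and upper ranges of chromosome 16 dose lay 2.65 SD apart in the squashed and 3.94 SD apart in the control library within state 2, but chromosome 17 gave 2.88 SD in the control and chromosome 20 gave 2.39 and 2.08 SD in control and squashed cells, so the separation cannot tell whether finer cell states are the cause. Doublets would hold more RNA, but upper-range cells of state 2 had at most 0.937 times the median UMIs of lower-range cells. When state 2 cells were ranked by the dose of 1 arm, at least 91.3% of the genes of the other arm were higher in the upper than in the lower 25% of cells, with median log2 ratios of 0.65 for 16p and 0.61 for 16q in the control library and 0.66 and 0.68 in the squashed library, beside 0.02 to 0.07 for genes of other chromosomes; in state 1 the lowest share was 85.7%, and the arms of chromosome 20 also reached 81.7% to 85.2% there, against 59.8% to 80% in state 2. A candidate explanation is thus that state 2 cells of both libraries differ in copies of the whole of chromosome 16, a hypothesis for which no DNA data were analysed here. The ratios of the fitted means, 0.695 and 0.714, do not fix the copy numbers, and whether confinement bears on the ranges stays untested. Over the common boundary lay 38.9% and 41.0% of state 2 cells but 28.8% and 24.2% of all cells. The fit itself put 35.9% and 45.2% of state 2 cells in the upper range.

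The metallothioneins MT2A (958 and 2535 CPM; 1.4, 1.38 to 1.42) and MT1X were higher in the squashed library, most of all in state 2, where MT2A stood at 721 and 3250 CPM (2.17, 2.13 to 2.21) and MT1X at 61.8 and 481 CPM (2.96, 2.83 to 3.09). Both have short transcripts on chromosome 16, but the MT2A ratio of state 2 exceeded that of state 1 by 1.39, while the median of all transcripts up to 500 nt differed by -0.19 between these states, which argues against length as the whole cause; the 0.78 of state 1 stays within what short transcripts showed. Among state 2 cells in the lower range of chromosome 16 the MT2A ratio was 2.24, which argues against copies of the chromosome in that state. A few very high cells are argued against for MT2A by the median cell of state 2, at 5 UMIs per 10000 in the control and 19 in the squashed library (a log2 ratio of 1.93), although the top 5% of squashed state 2 cells held 35.2% of its UMIs, against 19.2% in the control, and 69.7% of those of MT1X, against 25.2%. A response of these cells to zinc, copper or stress after confinement may be a cause and was not tested, and a difference in culture or medium stays open with 1 library per group.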
